A study of Mus musculus with 6 samples.

How the data were processed

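RNA was measured by bulk sequencing of whole liver from 6 C57BL/6J mice kept on a high-fat diet with carbon tetrachloride for 12 weeks, a model of metabolic dysfunction-associated steatohepatitis with fibrosis. Per the labels, 3 mice received an isotype control antibody and 3 an antibody against PD-1, every 3 days. Libraries were made with ribosomal RNA depletion and a directional kit, per the labels' protocols. Groups were taken from the sample titles and the series design. The treatment field of anti-PD-1 replicates 2 and 3 gives another number after "PD" than that of replicate 1, which was read as a spreadsheet fill error because the titles name PD-1 for all 3.

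The submitters' processing notes name Trimmomatic 0.38, RSEM 1.3.0, Bowtie2 and edgeR with the GRCm39 build, without stating their roles or order. The deposited signal is 1 normalized value per gene and library for 21512 genes. The values were whole multiples of the value of 1 read in each library for 100% of entries, within 0.001 read, so whole counts could be recovered, called reads here. Whether they are observed reads or rounded estimates cannot be seen from the values. The trimmed-mean (TMM) factors recomputed from these reads were the same to 3 decimals as those implied by the deposited columns, so the unit is CPM of a TMM-scaled library. Recovered depth was 15528364 to 20779319 reads per library, and the 10 most abundant genes took 15.1 to 17.8% of them. A limit of 3 reads corresponds to 0.144 to 0.2 units, and this limit covers counting error only. Every gene in the table had at least 6 reads in total.

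Gene symbols came from a table of names keyed by gene identifier, which matched 21407 identifiers. The other identifiers held 1.2 to 2.7% of reads per library. The reference sequence at hand was of an older build than the one the submitters name, so it served only to compare transcript sequences (BLAST 2.17.0), and no coordinates are given.

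Before the data were examined, the test, the alternatives, 45 gene lists and the rule for naming genes were fixed. Genes with at least 1 unit in at least 3 libraries were tested (13990 genes), a unit being 1.001 on the deposited scale. The test was limma 3.58.1 with an intensity trend on log2(value + 0.5 unit), in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale and understate changes of low genes. Gene lists with at least 5 tested genes (40 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Calls by fry refer to its directional test unless its mixed test is named. Group means are given with the SD over 3 mice, except where single libraries or means alone are given. Exact permutation of 3 against 3 cannot give a p under 0.1, so p-values come from the models across genes.

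The named genes are, per direction, up to 12 genes past the threshold, filled to 10 by the smallest unadjusted p where fewer passed, leaving out unnamed gene models. To these were added up to 4 genes with the smallest unadjusted p from each called list and from 6 lists of prior interest, and 18 genes fixed in advance. The rule named 120 genes, of which the text gives a part. Genes outside it are said to have been chosen after their values were seen.

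The titles number the mice 16, 17 and 18 in the control group and 20, 21 and 22 in the anti-PD-1 group, so they share no number. The replicate numbers 1 to 3 used here follow that order within each group. The labels do not say that this order marks a litter, cage or day. The deviations from the group means correlated at 0.15, 0.13 and 0.25 for libraries of the same number. This was the only 1 of the 6 possible pairings with every correlation over 0.1, and by that rule, set beforehand, the numbers were treated as pairing the mice. The pairing therefore rests on the values alone. A fit with the replicate number as a block was run beside the unpaired fit, which stayed the main one.

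Alternatives changed the pseudocount (0.1 and 2 units), the filter (none, or 5 units), the scaling between libraries, the limma settings, the threshold and the block, and left out each library in turn. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads. The edgeR test was run with TMM factors recomputed on the tested genes and then with the authors' factors over all genes. Both are given, since the choice between them was made after both outcomes were seen. Leaving out both libraries numbered 1 was also added after seeing the data, as were list tests with no filter together with anti-PD-1 replicate 1 left out or with an estimated correlation.

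limma with and without the block, edgeR, DESeq2 and camera were tried on simulated counts drawn from the real means, with 200 of 13990 genes changed. limma recovered 8% of genes changed 1.5-fold, 32% of those changed 2-fold, 76% at 3-fold and 90% at 4-fold, with 9 false calls. edgeR recovered 8, 34, 76 and 90% with 10 false calls. The blocked fit recovered 4, 30, 68 and 88% with 16 false calls, and DESeq2 20, 46, 80 and 92% with 32 false calls. In a second simulation, a list raised 1.5-fold was called by camera at an adjusted p of 1.95e-13, and at 0.0392 with an estimated correlation, with 0 other lists called. The simulated genes were drawn independently of each other. In the real data the estimated correlation within called lists was 0.09 to 0.89, so the simulation cannot show how often camera calls lists falsely here. Replicate libraries differed by far more than sampling noise (chi-square per degree of freedom 14.3 to 48.9), so none was counted as a repeat of another. Figures were drawn with matplotlib 3.10.9.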

Results

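Whole-liver RNA of 3 mice given an isotype control antibody and 3 mice given anti-PD-1, which blocks an inhibitory receptor of activated T cells, was compared after 12 weeks of high-fat diet and carbon tetrachloride. Recovered depth was 18428003, 17694425 and 20435097 reads for isotype control replicates 1 to 3 and 19153897, 15528364 and 20779319 for anti-PD-1 replicates 1 to 3. Values below are CPM of a TMM-scaled library, as mean ± SD over 3 mice unless single libraries or means alone are given. The comparison addresses how liver gene expression differs when PD-1 is blocked during the development of steatohepatitis and fibrosis.

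After anti-PD-1, the lists of interferon-gamma response and antigen presentation genes were called higher (23 of 23 and 17 of 17 genes positive), and those of fatty acid synthesis and resident Kupffer cells lower (15 of 17 and 8 of 11 negative). None of these 4 calls held with an estimated correlation (adjusted p = 0.627 with an estimated correlation for each). The Kupffer cell call also ended without isotype control replicate 1 (camera adjusted p = 0.0739) and with the filter of 5 units (0.0721). On the Kupffer list anti-PD-1 replicate 1 (-0.422 against the control mean on the log2 scale) lay no lower than isotype control replicate 2 (-0.424). Anti-PD-1 replicate 1 had by far the highest values on both immune lists, while on the interferon-gamma list anti-PD-1 replicate 2 (0.30 above the control mean on the log2 scale) lay no higher than isotype control replicate 1 (0.31). At the level of single genes, only the pseudogene Gm5537 passed the limma threshold (1 gene higher, 0 lower, of 13990 tested), and with the replicate block 27 genes were higher and 13 lower. The pairing behind that block was accepted from these same values, so no conclusion is drawn from the blocked counts. The fibrillar matrix and stellate cell lists did not pass the main test.

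The limma count of 1 higher and 0 lower compares with 705 and 873 genes at an unadjusted p under 0.05, against 700 expected by chance in both directions together. That count varies widely: other divisions of the same libraries gave 106 to 1148 such genes by limma, against 1578 in the real division. The divisions are too few for a share under 0.05. edgeR on recovered reads gave 1 higher and 0 lower with the authors' factors, and 0 and 0 with factors recomputed on the tested genes (763 and 861, and 794 and 832, at an unadjusted p under 0.05). DESeq2 gave 147 higher and 109 lower (874 and 724 unadjusted). In the simulation DESeq2 recovered more of the changed genes but made 32 false calls, against 9 by limma and 10 by edgeR. In 17.1% of tested genes the 3 anti-PD-1 values all lay on one side of the 3 control values, against 10% by chance. Without anti-PD-1 replicate 3 no gene was called, and without anti-PD-1 replicate 1 the counts were 24 higher and 6 lower.

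Gm5537 had 0 reads in each control library and 137, 136 and 122 reads in the anti-PD-1 libraries (7.32 ± 1.51, n = 3), at least 45.1-fold higher against a limit of 3 reads per library (limma adjusted p = 0.00279, and 0.0633 without anti-PD-1 replicate 3). Its 1252-base transcript is 100% identical to part of the transcript of Pgk1, a glycolytic enzyme gene, so its reads cannot be assigned with certainty. Pgk1 itself had 5470, 4181 and 6000 reads in the controls and 5095, 3601 and 5103 after anti-PD-1.

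Among the genes closest to the threshold, Skil, an inhibitor of SMAD signalling downstream of TGF-beta, was at 55.5 ± 5.09 in controls and 119 ± 17.2 after anti-PD-1. Its log2 fold change was 1.09 ± 0.13 (SE), with a limma adjusted p of 0.129 and of 0.0298 with the replicate block. Nfil3, a transcription factor tied to the circadian clock and to innate lymphoid cells, was at 40.9 ± 6.78 and 107 ± 23.7 (adjusted p = 0.129, and 0.0298 with the replicate block). Slc17a8 was at 41.0 ± 11.03 and 10.6 ± 2.14, and Anks4b at 98.6 ± 17.96 and 35.8 ± 9.23, each with an adjusted p of 0.129, and 0.0298 with the replicate block. Iffo2 was at 30.2 ± 4.34 and 13.2 ± 2.70 (adjusted p 0.0462 with the replicate block). Slc2a1, the glucose transporter GLUT1, was at 12.0 ± 2.06 and 30.9 ± 5.12, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 340 ± 118 and 120 ± 12.4. Neither passed in the limma fit (adjusted p = 0.129 for both) or with the replicate block. DESeq2 called all 7 of these genes, with adjusted p from 5.7e-11 for Slc17a8 to 3.11e-05 for Iffo2, and edgeR called none of them (adjusted p = 0.152 to 0.163). The anti-PD-1 values of these 7 genes all lay outside the control range. They were picked by smallest p, which favours such separation, so it adds no support. Shld2, Csad, Tcim and Depp1, also at a limma adjusted p of 0.129, did not pass with the replicate block (0.0553, 0.0622, 0.0729 and 0.0502). Of 116 named genes with a test, 6 besides Gm5537 passed with that block, whose pairing was accepted from these same values.

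**Figure D1:**
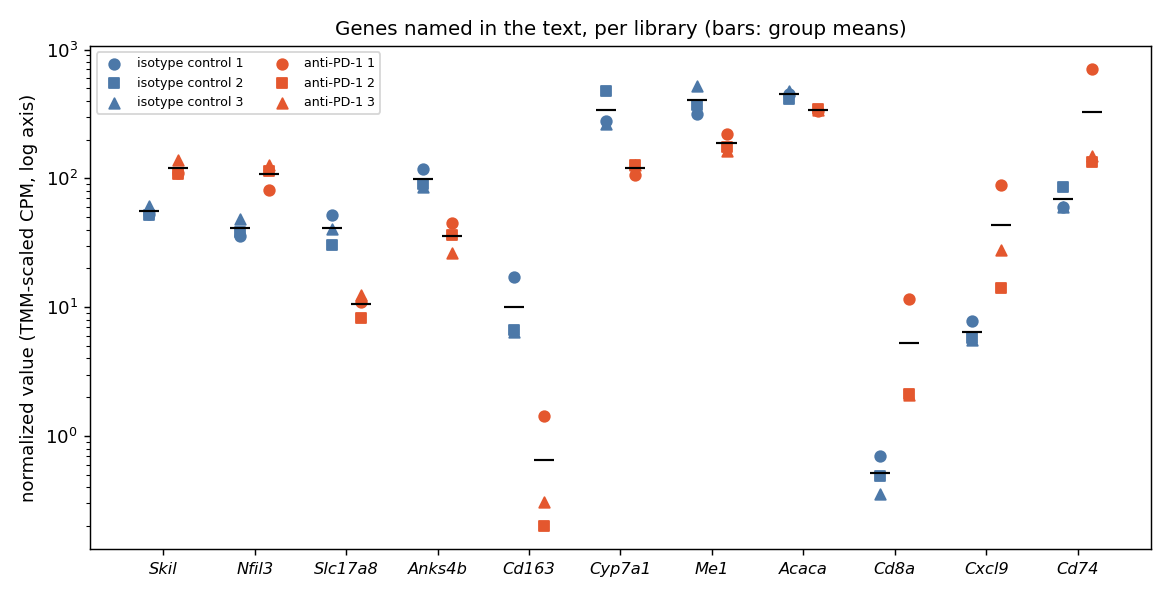
Normalized values (TMM-scaled CPM, log axis) of 11 genes in each of the 6 libraries, with bars at the group means. Skil and Nfil3 lie higher and Slc17a8, Anks4b, Cd163, Cyp7a1, Me1 and Acaca lower in all 3 anti-PD-1 libraries, while Cd8a, Cxcl9 and Cd74 are highest in anti-PD-1 replicate 1.

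Of the 40 lists tested, camera called 15 higher and 5 lower after anti-PD-1. None of the 20 calls held with an estimated correlation (adjusted p = 0.627 to 0.755 with an estimated correlation) or with fry's directional test. When each library was left out in turn, 6 of the 20 held. The mixed test of fry, which asks for no shared direction, put 3 lists under 0.05. These were de novo lipogenesis, bile acids and hepatocyte identity (fry mixed adjusted p = 0.0472 each), of which camera called only lipogenesis. Other divisions of the same 6 libraries gave 8 to 22 called lists. The smallest camera adjusted p of each such division ranged from 2.34e-24 to 6.9e-07, against 5.22e-09 for the real division.

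All 23 tested genes of the interferon-gamma response list had positive log2 fold changes, 11 of them at an unadjusted p under 0.05 by limma, with 0 past the adjusted threshold by limma or edgeR and 1, Cxcl9, by DESeq2 (median 0.91, camera adjusted p = 5.22e-09). The adjusted p was 0.627 with an estimated correlation. Cxcl9, a chemokine that draws T cells, was at 6.40 ± 1.29 in controls and 88.6, 14.2 and 27.8 in anti-PD-1 replicates 1 to 3. All 17 genes of the MHC class I and II list were likewise positive (median 0.77, camera adjusted p = 8.52e-09, and 0.627 with an estimated correlation). That list shares Tap1 with the interferon-gamma list, so the results are not independent. Cd74, the class II invariant chain, was at 68.7 ± 15.4 in controls and at 708, 134 and 148 after anti-PD-1, and H2-Q4 was at 27.2 ± 3.66 and 48.7 ± 12.6. Without anti-PD-1 replicate 1 the medians of these lists were 0.45 and 0.49, and both calls held.

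The 5 tested CD8 and cytotoxic genes had a median log2 fold change of 1.29 (camera adjusted p = 0.00343, and 0.627 with an estimated correlation). Adjusted over the list alone, 2 of them passed by limma, and over all genes 0 by limma and 2, Cd8a and Gzmb, by DESeq2, with 3 at an unadjusted p under 0.05 by limma. The median was 0.60 with a pseudocount of 2 and 1.95 with 0.1, and the call held. Of the 5 genes, Cd8a and Gzmb reached the filter's 1 unit in anti-PD-1 libraries only, so the filter let in genes that were high in that group. With no filter, all 19 genes were positive (median 0.97, camera adjusted p = 4.25e-07, and adjusted p = 0.565 with an estimated correlation), and the median was 0.31 (0.0058) when anti-PD-1 replicate 1 was also left out. Cd8a was at 0.51 ± 0.18 in controls and 11.7, 2.13 and 2.07 after anti-PD-1, and Gzmb, the granzyme B gene, at 0.32 ± 0.12 and 1.56 ± 0.69. The T cell list had a median of 1.25 (camera adjusted p = 0.0333, 0.076 with the replicate block, 0.627 with an estimated correlation). Its call also ended without isotype control replicate 2 (0.0564), isotype control replicate 3 (0.0719) or anti-PD-1 replicate 1 (0.077, median 0.64), with a pseudocount of 2 (0.0561) and with camera on ranks (0.0616). Of its 5 tested genes, 2 reached 1 unit in anti-PD-1 libraries only. With no filter, 21 of 22 genes were positive (median 0.90, camera adjusted p = 3.16e-07, and adjusted p = 0.565 with an estimated correlation), and the median was 0.30 (0.0024) when anti-PD-1 replicate 1 was also left out. The checkpoint receptor list had a median of 0.62 (camera adjusted p = 0.0226, 0.0748 without isotype control replicate 1, 0.241 without anti-PD-1 replicate 1, 0.627 with an estimated correlation). That median was 0.34 without anti-PD-1 replicate 1 and 0.94 without isotype control replicate 3. Cd274, which encodes the PD-1 ligand PD-L1, was at 3.04 ± 0.60 in controls and at 29.8, 4.99 and 4.40 after anti-PD-1. Pdcd1, the gene of PD-1 itself, fell under the filter, with values of 0.38, 0.27 and 0.10 in controls and 5.43, 0 and 0.62 after anti-PD-1. Cd4, Ifng and Foxp3 also fell under the filter, at 0.71 ± 0.19, 0.07 ± 0.03 and 0.30 ± 0.14 in controls and 1.47 ± 1.06, 0.26 ± 0.40 and 0.56 ± 0.65 after anti-PD-1.

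The monocyte and infiltrating macrophage list had a median of 0.61 (camera adjusted p = 0.00394, 0.627 with an estimated correlation), which was 0.04 with an adjusted p of 0.851 without anti-PD-1 replicate 1 and 0.95 without anti-PD-1 replicate 2. Of 11 Kupffer cell genes, 8 had negative log2 fold changes (median -0.59, camera adjusted p = 0.00343, 0.0739 without isotype control replicate 1, 0.627 with an estimated correlation). The median was -0.37 without that library, and with the filter of 5 units it was -0.13 and the call ended (0.0721). Of the 11 genes, 4 passed by limma when adjusted over the list alone, and over all genes 0 by limma and 3 by DESeq2, with 6 at an unadjusted p under 0.05 by limma. Cd163, a haemoglobin scavenger receptor of resident macrophages, was at 17.3, 6.60 and 6.39 in controls and 1.44, 0.20 and 0.31 after anti-PD-1 (limma adjusted p = 0.129, and 0.0298 with the replicate block). Timd4 was at 3.06 ± 1.16 and 0.51 ± 0.32, and Marco at 8.53 ± 5.06 and 1.44 ± 1.14. The lipid- and scar-associated macrophage list had a median of -0.11 (camera adjusted p = 0.454) and was called lower without anti-PD-1 replicate 1 (-0.25, adjusted p = 0.0111), while its median turned to 0.10 without isotype control replicate 1 and 0.05 without anti-PD-1 replicate 2, with Trem2 at 5.84 ± 3.87 and 7.18 ± 2.57.

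Of 17 genes of de novo lipogenesis, 15 had negative log2 fold changes, 7 of them at an unadjusted p under 0.05 by limma, 6 of those past the threshold when adjusted over the list alone, and over all genes 0 by limma and 3 by DESeq2 (median -0.38, camera adjusted p = 5.57e-05, 0.627 with an estimated correlation). Without isotype control replicate 3 the median was -0.20 and the call held (0.00318). In the other direction, 1 gene had an unadjusted p under 0.05, Srebf1, a transcription factor of lipid synthesis genes, named here after its values were seen, at 429 ± 75.3 in controls and 719 ± 226 after anti-PD-1. It did not pass when adjusted over the list alone. Me1, which supplies NADPH, was at 403 ± 104 and 187 ± 30.4, Acaca, the acetyl-CoA carboxylase gene, at 450 ± 33.7 and 340 ± 7.75, and Fasn, the fatty acid synthase gene, at 2520 ± 270 and 1933 ± 192. The lipid droplet list had a median of -0.36 (camera adjusted p = 0.0156, 0.0719 with a median of -0.205 without isotype control replicate 3, 0.125 with the filter of 5 units, 0.627 with an estimated correlation), with the lipid droplet coat gene Plin2 at 489 ± 81.5 and 378 ± 24.4. The periportal list, which holds gluconeogenic and urea cycle genes, was higher (median 0.31, camera adjusted p = 0.0031, 0.0691 without isotype control replicate 2, 0.627 with an estimated correlation). Its median was 0.48 without anti-PD-1 replicate 1 and 0.16 without anti-PD-1 replicate 3, and the call held. G6pc was at 982 ± 89.9 and 1458 ± 181, and Pck1 at 2534 ± 899 and 4231 ± 1153. The endoplasmic reticulum stress list was higher (median 0.15, 0.24 without anti-PD-1 replicate 1 and 0.06 with quantile normalization, camera adjusted p = 0.00343, 0.627 with an estimated correlation), with Atf3 at 7.17 ± 1.73 and 17.1 ± 4.63.

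The fibrillar matrix list, with 24 of 36 genes positive, had a median of 0.16 and was not called (camera adjusted p = 0.131). It was called higher without isotype control replicate 2 (0.24, adjusted p = 0.00538), anti-PD-1 replicate 2 (0.30, 0.000362) or anti-PD-1 replicate 3 (0.22, 0.0258). Without anti-PD-1 replicate 1 the median turned to -0.11 (0.077), and without isotype control replicate 1 it was 0.02 (0.915). Without both libraries numbered 1, a setting chosen after seeing the data, its median was -0.23 and it was called lower (adjusted p = 0.000158). Col1a1 was at 60.4, 121 and 65.9 in controls and 153, 60.4 and 58.7 after anti-PD-1. The stellate cell list had a median of 0.05 (camera adjusted p = 0.53), which was 0.005 without anti-PD-1 replicate 1, 0.13 (0.0542) without anti-PD-1 replicate 2, 0.077 (0.13) without isotype control replicate 2 and -0.049 without both libraries numbered 1, with Acta2, a myofibroblast marker, at 8.39 ± 6.40 and 7.54 ± 5.50. Timp1, an inhibitor of matrix proteases, was at 1.06 ± 0.45 and 1.52 ± 0.93. The spread of Col1a1 and Acta2 within a group exceeded the difference between the group means.

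Of 24 proliferation genes, 20 had negative log2 fold changes (median -0.51, camera adjusted p = 0.00078, 0.34 with a median of -0.324 with the filter of 5 units, 0.627 with an estimated correlation). Isotype control replicate 1 stood apart on this list (0.57 above the control mean, against -0.37 and -0.20). Anti-PD-1 replicate 1, at 0.009, lay above isotype control replicates 2 and 3. Without isotype control replicate 1 the median was -0.28, and without anti-PD-1 replicate 3 it was -0.33, and both calls held (0.0281 and 0.0412). Mki67 was at 46.6, 15.2 and 17.7 in controls and 26.0, 10.3 and 6.88 after anti-PD-1. The clock list had a median of 0.42 (camera adjusted p = 0.0226, 0.627 with an estimated correlation), and isotype control replicate 1 stood apart in it: without that library the median was -0.06 with an adjusted p of 0.0928, and without both libraries numbered 1 it was 0.13 and the list was called higher (0.00596). The call also ended without anti-PD-1 replicate 2 (0.27, adjusted p = 0.0924), and the median was 0.66 without isotype control replicate 2 and 0.69 without isotype control replicate 3. Cyp2e1, Alb and Afp, markers of pericentral, mature and fetal hepatocytes, were at 3467 ± 1276, 58679 ± 11031 and 2.45 ± 1.06 in controls and 4093 ± 576, 49009 ± 3331 and 2.16 ± 0.33 after anti-PD-1, and none passed the test.

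**Figure D2:**
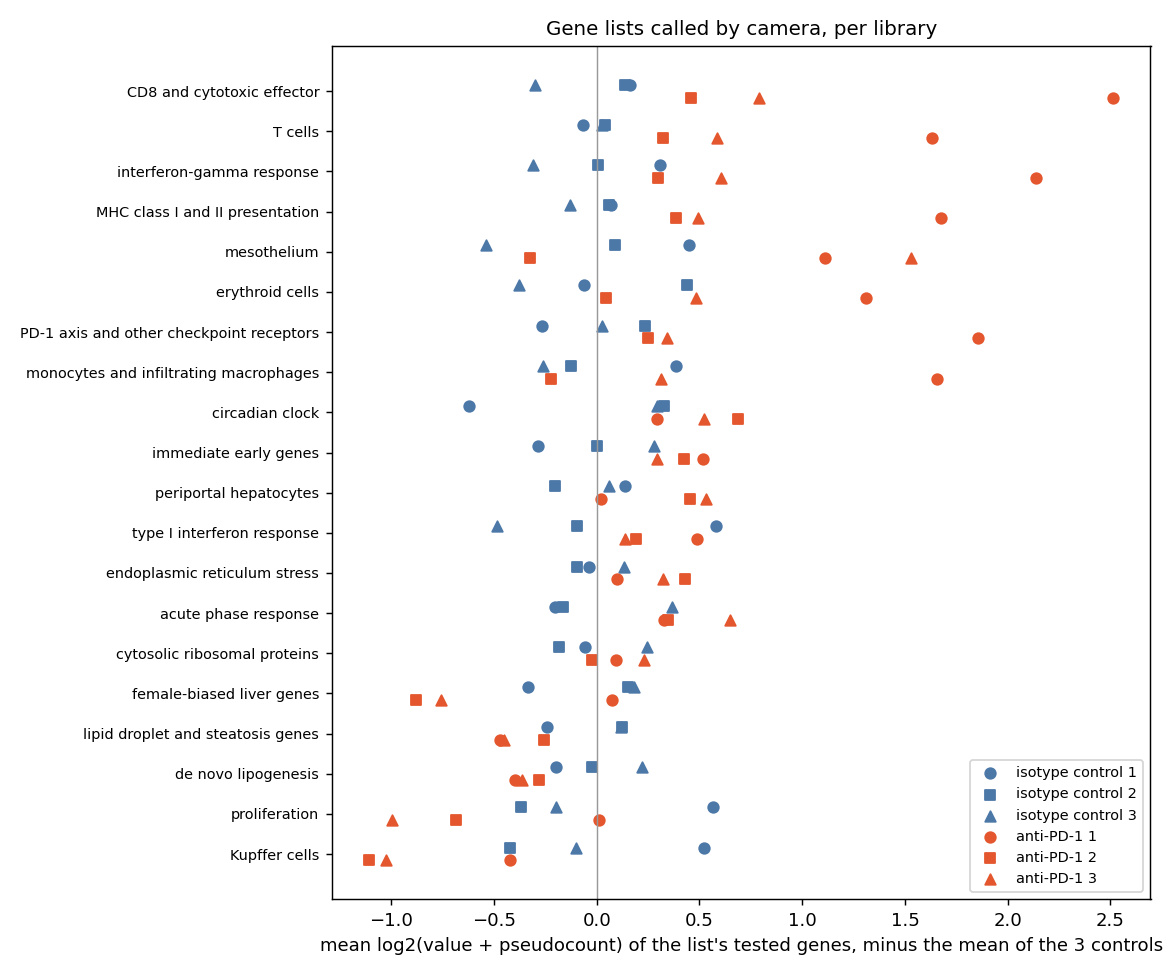
Mean log2(value + 0.5 unit) over the tested genes of each of the 20 called lists, minus the mean of the 3 controls, for each of the 6 libraries. Anti-PD-1 replicate 1 lies at 2.51 for the CD8 and cytotoxic list and 2.14 for the interferon-gamma list, and the other anti-PD-1 libraries between 0.30 and 0.79 for both, where isotype control replicate 1 lies at 0.31 for the interferon-gamma list.

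**Figure D3:**
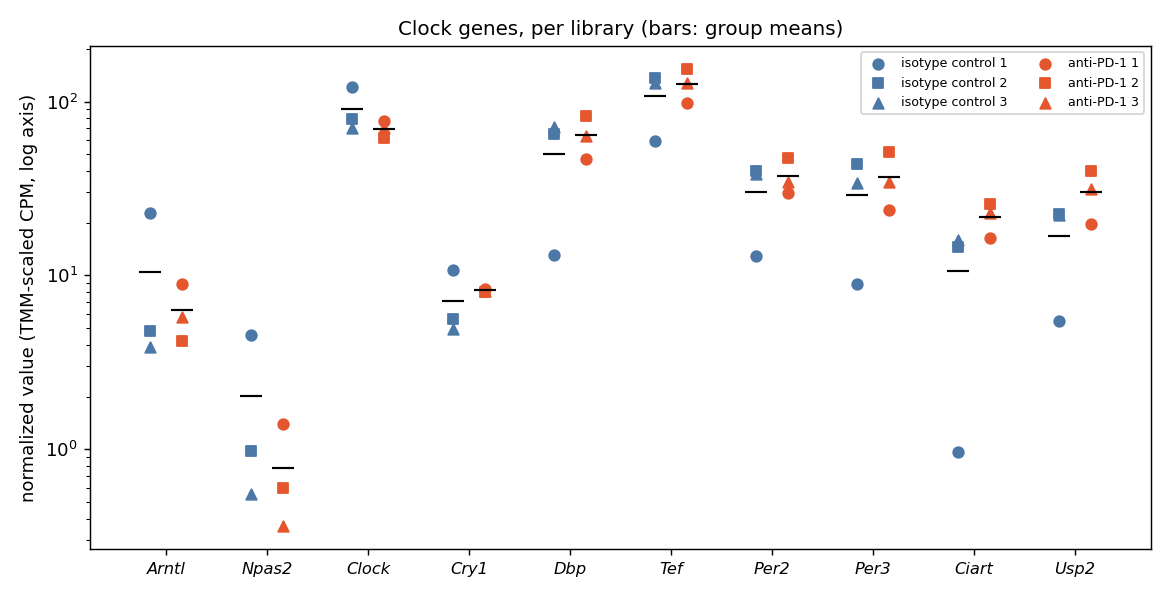
Normalized values (TMM-scaled CPM, log axis) of 10 clock genes, chosen after their values were seen, in each of the 6 libraries, with bars at the group means. Isotype control replicate 1 has the highest Arntl (22.9) and the lowest Ciart (0.97) of all 6 libraries.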

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

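Leaving out both libraries numbered 1 was chosen after seeing the data, and the edgeR fits with the authors' and with recomputed factors were set side by side after both outcomes were seen. The count of genes higher and lower was 1 and 0 in the main test. It was 19 and 14 with library weights, 147 and 109 with DESeq2, 27 and 13 with the replicate block, 97 and 36 without both libraries numbered 1, and 0 higher by edgeR with recomputed factors. With 1 library left out it ranged from 0 to 24 higher and from 0 to 6 lower: 24 and 6 without anti-PD-1 replicate 1, 2 higher without isotype control replicate 2, and 0 without anti-PD-1 replicate 3. All other settings gave 1 and 0. Of the 40 blocked calls, 34 were among the 256 by DESeq2. The cause of these differences was not tested.

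Called lists numbered 15 higher and 5 lower. With an estimated correlation and with fry both numbers were 0. With no filter on low values 8 lists were lower, with the filter of 5 units 2, and without both libraries numbered 1 there were 10. With 1 library left out, 9 to 17 lists were higher and 3 to 11 lower. The extremes came without anti-PD-1 replicate 1 (9 higher, 11 lower), without anti-PD-1 replicate 2 (17 higher) and without isotype control replicate 3 (3 lower), and 8 were lower without isotype control replicate 1. The interferon-gamma, MHC, lipogenesis and endoplasmic reticulum stress lists (4 of 20) kept their call in every setting except the estimated correlation and fry, as did the CD8 list where it kept the 5 genes needed. The fibrillar matrix list reversed to a median of -0.225 (camera adjusted p = 0.000158) without both libraries numbered 1. With no filter and anti-PD-1 replicate 1 left out, a setting chosen after seeing the data, the monocyte list turned to -0.003 and was not called.

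With the replicate block, 3 list calls ended (T cells, erythroid, female-biased), 6 named genes besides Gm5537 passed, and no other call among the named genes and lists changed. Of 116 named genes with a test, 113 to 116 kept their sign in each setting that tested them all. Other scalings moved the median log2 fold change of all genes to between -0.02 and 0.01. In the simulation at this depth and spread, 32% of genes changed 2-fold were recovered.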

Other observations

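The tests of explanations for Gm5537, for anti-PD-1 replicate 1 and for the clock and lipogenesis lists, the count of splits with the replicate block and the setting without both libraries numbered 1 were chosen after the results were seen. The clock test first used only the fit without isotype control replicate 1, and the fit without both libraries numbered 1 was added to it after that outcome was seen.

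Further lists were called higher. The type I interferon list had a median of 0.24 (camera adjusted p = 0.0181, and 0.755 with an estimated correlation). Its call ended without isotype control replicate 2 (0.0939), isotype control replicate 3 (0.891) or anti-PD-1 replicate 1 (0.217), with medians of 0.184, -0.011 and 0.157, and the median was 0.562 without isotype control replicate 1. The acute phase list had a median of 0.15 (camera adjusted p = 0.0184, and 0.627 with an estimated correlation; 0.339 without isotype control replicate 2 and 0.188 without anti-PD-1 replicate 3), with the metallothionein gene Mt2 at 0.81, 8.71 and 19.3 in controls and 35.1, 45.4 and 67.9 after anti-PD-1. Its median was 0.038 and 0.059 where the call ended, and 0.244, 0.242 and 0.26 without isotype control replicate 1, isotype control replicate 3 and anti-PD-1 replicate 1. Immediate early genes (median 0.41), ribosomal proteins (0.11), erythroid genes (0.68) and mesothelium (0.74) were called at camera adjusted p of 0.00489, 0.0154, 0.0285 and 0.0181. Their adjusted p was 0.627, 0.755, 0.627 and 0.627 with an estimated correlation. The immediate early call ended without anti-PD-1 replicate 1 (0.085), and the ribosomal call without isotype control replicate 1 (0.0907), isotype control replicate 2 (0.698) or anti-PD-1 replicate 3 (0.336). The erythroid and mesothelium calls ended without isotype control replicate 3 (0.188 and 0.155) or anti-PD-1 replicate 1 (0.194 and 0.185), and that of mesothelium also without anti-PD-1 replicate 3 (0.176). The erythroid median was 0.291 without anti-PD-1 replicate 1 and 1.036 without anti-PD-1 replicate 2. The mesothelium median was 0.33 without anti-PD-1 replicate 3, 0.43 without isotype control replicate 3 and 1.303 without anti-PD-1 replicate 2. With a pseudocount of 2 the immediate early median was 0.254 and that of mesothelium 0.489, and both calls held. The ribosomal median was 0.025 without isotype control replicate 2, 0.034 without anti-PD-1 replicate 3 and 0.232 without isotype control replicate 3, and its call also ended with quantile normalization (0.0531). The erythroid call also ended with the replicate block (adjusted p = 0.0728). The female-biased list was lower (median -0.35, camera adjusted p = 0.0441, 0.0728 with the replicate block, 0.627 with an estimated correlation), with Cyp2b9 at 38.6 ± 5.24 in controls and 66.7, 4.26 and 2.17 after anti-PD-1. That call ended without isotype control replicate 2 (0.13) or 3 (0.155) and without anti-PD-1 replicate 2 (0.309) or 3 (0.0709). It also ended with no filter on low values (0.159), equal totals (0.0769), quantile normalization (0.0725) and camera on ranks (0.0941), and the median was -0.155 without isotype control replicate 3, -0.11 with no filter, -0.618 without isotype control replicate 1 and -0.623 without anti-PD-1 replicate 1. The male-biased list was not called (median 0.252, camera adjusted p = 0.343). Anti-PD-1 replicate 1 lay at -0.896 on it, against 0.738 and 0.903 for the other anti-PD-1 libraries, and the controls lay at 0.664, -0.05 and -0.613. It was called higher without anti-PD-1 replicate 1 (0.84, 2.96e-05) or isotype control replicate 1 (0.469, 0.0162), and its median turned to -0.107, -0.008 and -0.036 without isotype control replicate 3, anti-PD-1 replicate 2 and anti-PD-1 replicate 3.

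Lists without a call included cholangiocytes (median -0.51, camera adjusted p = 0.106), cholesterol biosynthesis (-0.11, 0.212), fatty acid oxidation (-0.07, 0.127), bile acids (-0.07, 0.0749), B and plasma cells (0.05, 0.876) and sinusoidal endothelium (0.06, 0.783). Leaving out 1 library brought some of these below the threshold, as did no filter for cholangiocytes (0.021) and bile acids (0.0492) and quantile normalization for bile acids (0.0312). With no filter and an estimated correlation, the adjusted p was 0.565 for each. With no filter and anti-PD-1 replicate 1 left out, it was 0.0058 for cholangiocytes and 0.692 for bile acids. Without isotype control replicate 1, cholesterol biosynthesis (-0.26, 7.5e-06) and cholangiocytes (-0.61, 0.00434) were called lower. Without anti-PD-1 replicate 1, cholesterol biosynthesis (-0.18, 0.0474), cholangiocytes (-0.65, 0.0272) and B and plasma cells (-0.53, 0.0369) were called lower, and bile acids were without anti-PD-1 replicate 2 (-0.14, 0.0221) or 3 (-0.20, 0.0291). The B and plasma cell median also turned negative without isotype control replicate 2 (-0.012) or 3 (-0.138), with no call.

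Other lists without a call in the main test were called in some settings. Without isotype control replicate 1, pericentral hepatocyte genes (-0.234, camera adjusted p = 0.00388, with a main median of 0.209) and mitochondrially encoded genes (-0.157, 0.0112) were lower and p53 targets higher (0.288, 0.000476). The mitochondrial median turned to 0.03 (0.821) without isotype control replicate 3. That of p53 targets turned to -0.119 (0.628) without isotype control replicate 2 and -0.023 (0.428) without isotype control replicate 3. NRF2 targets were lower without isotype control replicate 2 (-0.192, 0.038) or anti-PD-1 replicate 1 (-0.22, 0.0214), as were liver tumour and fetal genes without the latter (-0.409, 0.0491). The liver tumour and fetal median turned to 0.118 (0.637) without isotype control replicate 1 and 0.031 (0.398) without anti-PD-1 replicate 2. Inflammatory cytokine genes were higher without anti-PD-1 replicate 2 (0.461, 0.0023) or 3 (0.363, 0.0192) and with no filter (0.326, 0.009). The main median of that list was 0.284 (0.106), and it turned to -0.113 (0.243) without anti-PD-1 replicate 1. With no filter and that library left out, the median was -0.108 (0.384). With no filter and an estimated correlation, the adjusted p was 0.685. Neutrophil genes were higher without anti-PD-1 replicate 2 (1.122, 0.00134) and with no filter (0.622, 0.00068). Their main median of 0.559 (0.106) became 0.14 (0.913) without anti-PD-1 replicate 1 and -0.048 (0.837) without both libraries numbered 1. With no filter, the adjusted p was 0.213 when anti-PD-1 replicate 1 was also left out and 0.565 with an estimated correlation. Hepatocyte identity genes were lower without anti-PD-1 replicate 3 (-0.083, 0.0161), and adipose genes with no filter (-0.741, 0.0415). The hepatocyte identity median turned to 0.107 (0.989) without anti-PD-1 replicate 1 and 0.017 (0.219) without isotype control replicate 3. The adipose adjusted p with no filter was 0.238 when anti-PD-1 replicate 1 was also left out and 0.685 with an estimated correlation. Among the genes that passed with the replicate block and were chosen here after their values were seen, Bcl6 was at 37.7 and 8.17, Hhex at 40.7 and 13.9, Tbx3 at 34.3 and 11.9, and Nfe2l2, the NRF2 gene, at 93.5 and 46.9 in controls and after anti-PD-1. Abcg5, a sterol transporter gene, was at 70.9 and 144.

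The 10 splits of 3 against 3 are too few for a share under 0.05. The real split called 1 gene and the highest other split 1, and 2 of the 10 splits called as many. For gene lists, 5 of the 10 splits called as many as the real 20, and the highest other called 22. The real split parts all 3 pairs, and with the replicate block it called 40 genes. The 3 other splits that part all pairs called 0, so 1 of the 4 reached that count, again too few for a share under 0.05. The pairing was itself accepted because deviations from the real group means correlated in these same values. The other splits are therefore not an equal reference for the real one, and no conclusion is drawn from these blocked counts.

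Gm5537 was read in all anti-PD-1 libraries and in no control library. A constant share of Pgk1 reads counted for the pseudogene is argued against: at the anti-PD-1 share of 2.78%, the controls would hold 436 reads, and they held 0. That comparison covers a constant share only. Whether Pgk1 reads were assigned to the pseudogene at a share that differed between libraries was not tested and stays open. A sequence difference among the mice in the Pgk1 family may have moved reads, but with 100% identity to Pgk1 and no reads at hand this cannot be told apart from expression of the pseudogene. Whether the groups came from different litters is not stated in the labels.

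Immune genes were highest in anti-PD-1 replicate 1. Against the mean of the other anti-PD-1 libraries, T cell and cytotoxic genes exceeded by a median log2 of 2.13, neutrophil genes by 2.23, MHC class II genes by 2.66 and haemoglobin genes by 1.45. Blood trapped in the sample, at the composition of the other mice, is argued against as the whole cause, since the T cell median exceeded that of haemoglobin by 0.69 and its lower quartile (1.75) lay above the highest haemoglobin gene (1.55). Lymphoid tissue in the sample may contribute: B cell genes exceeded by 1.38, which is 0.76 less than T cell genes with overlapping quartiles, so it cannot be told apart from infiltration. Blood richer in leukocytes and a stronger response of this mouse to treatment stay open and untested.

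Isotype control replicate 1 differed from the other 5 libraries in clock genes, chosen after their values were seen. Arntl was higher by 2.02 and Npas2 by 2.04 on the log2 scale, while Dbp was at -2.27, Per3 at -1.97 and Ciart at -3.70. Without that library the clock list median was -0.055 and its call ended, but without both libraries numbered 1 the median was 0.128 and the list was again called higher (camera adjusted p = 0.00596). Whether another clock phase in that mouse accounts for the list's call therefore stays open. The lower lipogenesis list is not accounted for in the same way, since its median was -0.429 without that library (camera adjusted p = 9.5e-09, and 0.627 with an estimated correlation in all 6).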
